A study of Caenorhabditis elegans with 2 samples.

How the data were processed

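The series holds chromatin immunoprecipitation sequencing from whole C. elegans fourth-stage larvae with a tagged hmg-1.1 gene, in 2 samples that the labels number as biological replicates of 1 group. The labels name an anti-GFP antibody, fragmentation by sonication, synchronisation by starving hatchlings, and a control experiment that is not analysed here. What was analysed are the authors' peak lists on the ce11 assembly: per replicate a ranked list and a thresholded list, and for both replicates together 2 ranked and 2 thresholded lists. Per the deposited file listing, the lists were derived from the replicate alignments and a control alignment, and the thresholded lists also from 1 further file that is not described. The aligner, the peak caller and their versions are not given in the sources used here.

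Each peak carries 4 kinds of value. The score deposited by the authors is a scaled IDR score, and every thresholded list starts at a score of 830. The signal deposited by the authors is an enrichment per peak whose scale is not stated, so it was used to rank and compare peaks within a list, and by rank between the replicates. The −log10 of the q-value was deposited by the authors as well, and 700 peaks of the conservative list (16.4%) have a q-value above 0.05, since that list was selected on IDR. The −log10 of the global IDR was deposited by the authors too. The summit position counts from the peak start and was turned into a 1-based coordinate. The lists hold no read counts, so depth per sample is unknown, and the intervals given cover counting error over peaks or genes only.

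The conservative list was the main list, with each replicate's own thresholded list beside it. It holds 4277 peaks with a median width of 376 bp. Peaks that touch were merged for overlaps and for naming, which left 4008 regions, 2383 in replicate 1 and 2768 in replicate 2. No interval was the same in both replicate lists. All peaks lay inside the 6 nuclear chromosomes of the reference. Gene positions came from Ensembl release 115 and sequence from the NCBI assembly of the same genome build. A gene start is the outermost annotated 5' end. Many worm transcripts are trans-spliced, so an annotated start can lie downstream of the promoter, which is why a distance of 500 bp was used.

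Placement was tested against 10000 circular shifts of the summits along each chromosome, two-sided, which keep the number and clustering of peaks. Gene shares (lists, chromosomes, divergent starts) were tested with Fisher's exact test, signal with 100000 permutations of the class labels, and summit position, base composition and 6-mers with exact binomial sign tests. Families of tests were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Intervals are 95% Wilson intervals. Annotation classes were given in a fixed order of precedence from the upstream 500 bp to the rest of the genome. Non-coding types with at least 10 genes were tested. Base composition was compared between the window centred on the summit and the mean of the windows of the same size 500 bp to either side. The 6-mers, both strands together, were compared with 1 of those flanks, drawn with seed 11. Pseudogenes were left out of the non-coding class. Nearby peaks and neighbouring genes are not independent, so Fisher's exact and sign test p-values over genes and peaks are smaller than independent units would give. With 1 group there is no test of a biological condition. Comparisons set peaks against the genome.

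The grouping, the tests, the 28 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The tests of the closing observations and some alternatives were not. The rule names the 25 strongest merged peaks that overlap both replicates' lists, by the protein-coding start within 500 bp of the summit, else a non-coding gene within 500 bp, else the gene around the summit. For each list it takes up to 4 members with the strongest peak and, where most members have none, up to 2 without. It also takes the hmg genes, the 5 strongest regions of each replicate that the other lacks, and the 10 6-mers with the smallest p in each direction. Examples in the text are drawn from these.

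Alternatives were the other thresholded series list, the stronger peaks by signal, a global IDR of at most 0.01, each single replicate, distances of 250 and 1000 bp, any transcript start, windows of 51 and 201 bp, flanks 1000 bp away, shifted windows, summits at gene starts only, lists stratified by chromosome and segment or with neighbours within 10 kb counted once against other genes in 10 kb bins, 3 gene families left out, a wider central segment, a reciprocal overlap of 50%, summits within 100 bp, and equal list lengths. Chosen after seeing the data were 1 summit per merged region, a q-value of at most 0.05, a global IDR of at most 0.001, leaving out summits near tRNA genes, and counting the nearest start alone.

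The functions were tested on simulated data. With 2000 summits placed at random, 0 of 20 runs were called for gene starts, 0 of 140 annotation classes, 0 of 90 gene types, and 1 of 20 runs for base composition. With part of the summits moved to gene starts, 10 of 10 runs were called. With 19973 genes, 48 of 50 changed lists and 1 of 230 unchanged lists were called. Genes were marked independently of each other there, so these counts do not cover summits shared by neighbouring genes or clustered list members. Planted shared peaks were recovered as an overlap of 60.3%, and a planted 6-mer took rank 1. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.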

Results

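HMG-1.1 is a high mobility group box protein, one of a family of small, abundant chromatin proteins that bend DNA with little regard for its sequence. Its genomic sites were mapped by chromatin immunoprecipitation and sequencing in Caenorhabditis elegans carrying, at the endogenous gene, an insertion that fuses EGFP and other tags to the protein, with an antibody against GFP. Whole fourth-stage larvae were collected at 48 hours, in 2 biological replicates that form 1 group. The 2 replicates are therefore the comparison between samples that the labels allow, and all other comparisons set peaks against genome positions, gene types and gene lists within a peak list. Of the peak lists called on both replicates together and thresholded on the irreproducible discovery rate (IDR), the one the authors call conservative held 4277 peaks in 4008 separate regions. The replicates' own thresholded lists held 2613 and 3082 peaks. The lists hold no read counts, so the sequencing depth is unknown. The signal is the authors' value for each peak. It was used to rank, describe and compare peaks within a list, and by rank between the replicates.

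The tagged gene itself lay among the sites. hmg-1.1 (WBGene00001971, chromosome II, 14250695 to 14251450, plus strand, ce11) had 4 peaks of the conservative list within 2000 bp. The strongest had its summit at -230 bp from the gene start (II, 14250356 to 14250647) with a signal of 342, rank 239 of 4277. Replicate 1 had 3 peaks within the same distance and replicate 2 had 4. The weakest of these in replicate 2 (-96 bp, signal 12.7, rank 2887 of 3082) overlapped its strongest, at -301 bp. The conservative peak at 1059 bp overlapped no peak of either replicate's thresholded list. Of the other hmg genes, hmg-1.2 had a summit within 500 bp of its start (signal 314), as did hmg-6 (203) and hmg-11 (127), while hmg-3 and hmg-4, which encode subunits of the FACT histone chaperone, had none, and neither did hmg-5, hmg-12 or hmg-20. The hmg-11 summit, at -236 bp, lay nearer to the start of the C-type lectin gene clec-140 (-211 bp) and counts for both genes. In the list of replicate 1, hmg-11 had no summit.

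Most regions found in one replicate were found in the other. Of the 2383 separate regions of replicate 1, 1957 (82.1%, 95% Wilson interval 80.5 to 83.6) overlapped a region of replicate 2 by at least 1 bp, against 1.965% after circular shifts along the chromosomes. Of the 2768 regions of replicate 2, 1960 (70.8%, 69.1 to 72.5) overlapped one of replicate 1, against 1.69% after shifts. Each two-sided permutation p was 0.0002, the smallest that 10000 shifts can give. Among the 1000 strongest regions of each replicate, 819 (81.9%, 79.4 to 84.2) overlapped. Across the 1952 regions present in both lists, Spearman's rho of the signal was 0.853; this is a correlation across regions, which are not independent replicates, and no p-value was attached to it.

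Regions listed in 1 replicate alone were weaker. There were 426 in replicate 1 (17.9%), with a median signal of 52.6 against 84.96 for the shared regions of that list, and 808 in replicate 2 (29.2%), with 59.0 against 100.2. The strongest in replicate 1 lay at -270 bp from the start of the ribosomal protein gene rps-4 (signal 124.7), followed by regions near the non-coding genes F58A3.6 and srpr-1.1 and the protein-coding genes mpz-3 and kin-14. In replicate 2 they lay at the shared start region of ekl-4 and the ribosomal protein gene rps-20 (172), at cdk-7 (155), which encodes a cyclin-dependent kinase, at srpr-1.1 and F13D12.11, and between genes on chromosome V (4063567 to 4063916, signal 130). At srpr-1.1 both replicates had a region, but the intervals did not overlap (III 4378883 to 4379038 in replicate 1, 4379075 to 4379270 in replicate 2). Of the 4008 regions of the conservative list, which was called on both replicates together, 1938 (48.4%) overlapped a region of both replicates' own lists, 915 a region of 1 of them and 1155 of neither.

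**Figure D1:**
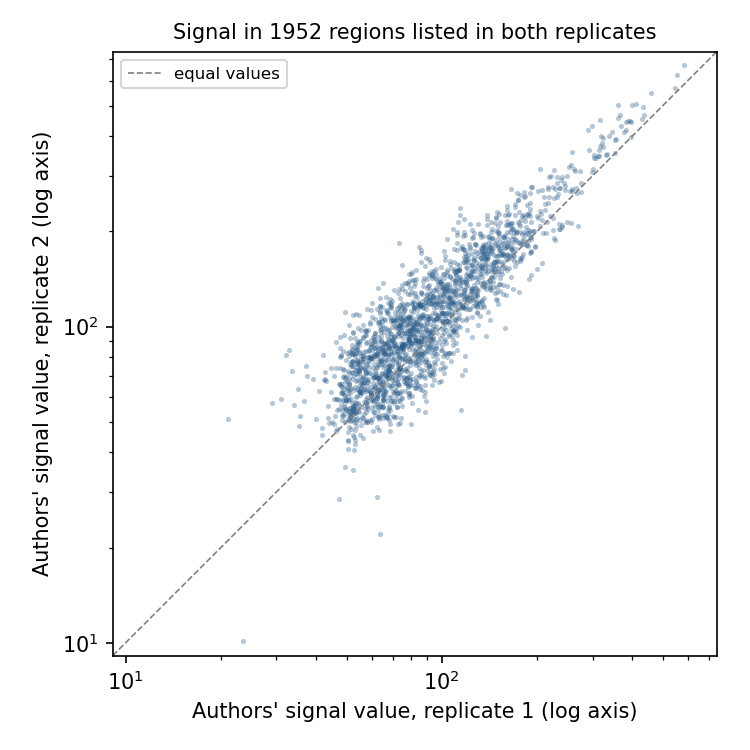
The authors' signal value of the 1952 regions listed in both replicates, replicate 1 on the x axis and replicate 2 on the y axis, both logarithmic; each point is a region and the dashed line marks equal values. The points lie along a single rising band (Spearman's rho 0.853).

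The strongest sites lay at gene starts and between genes, with 15 of 25 on the X chromosome. Among the 25 strongest regions that were also in both replicates' lists, 6 lay at protein-coding gene starts, and the first was at -283 bp from the start of rpl-3 (WBGene00004414), a large ribosomal subunit protein gene, at III 3867410 to 3867727, with a signal of 1240.3. The second lay upstream of cox-5A (1170.0), a cytochrome c oxidase subunit gene, at III 12905040 to 12905356. The others were at the shared start region of Y17G9B.5 and rpl-20 (1022), at tasp-1 (939), at mog-4 (936), an RNA helicase gene of the germline sex decision, and between F44E5.5 and F44E5.4 (737), a pair of Hsp70 genes. A further 2 lay at the spliced leader RNA genes sls-2.1 (840.0) and sls-2.4 (752), and 2 near non-coding genes, WBGene00195021 on IV (831) and C18A11.13 on X (769). Of the 15 on X, 11 had no gene within the limits used for naming. The strongest of these were at X 11093937 to 11094408 (1125), X 14525570 to 14526199 (936), X 13700625 to 13701121 (924) and X 806505 to 806854 (895). Another 3 on X lay in the introns of mom-1 (885) and Y41G9A.17 (814) and in a coding exon of pks-1 (763), and the remaining intergenic one lay on IV at 4727905 to 4728186 (792).

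Summits were concentrated just upstream of protein-coding genes. Of the 4277 summits, 1670 (39.0%) lay within 500 bp of a protein-coding gene start, 2.13 times the 18.3% found after circular shifts (two-sided permutation p = 0.0002, the smallest the shifts can give). The shares in the replicates' own lists were 40.3% and 42.02% (mean 41.2% ± 1.19, SD, n = 2). The conservative list marked 1954 of 19973 protein-coding genes (9.78%), and the replicates' shorter lists marked 1210 (6.06%) and 1459 (7.30%). Relative to the nearest start within 1000 bp, the 2177 summits had a median position of -174 bp (quartiles -356 and -34), and 1739 lay upstream against 438 downstream (79.9%; exact binomial p = 1.21e-182, two-sided). The medians in the replicates were -186 and -184 bp.

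**Figure D2:**
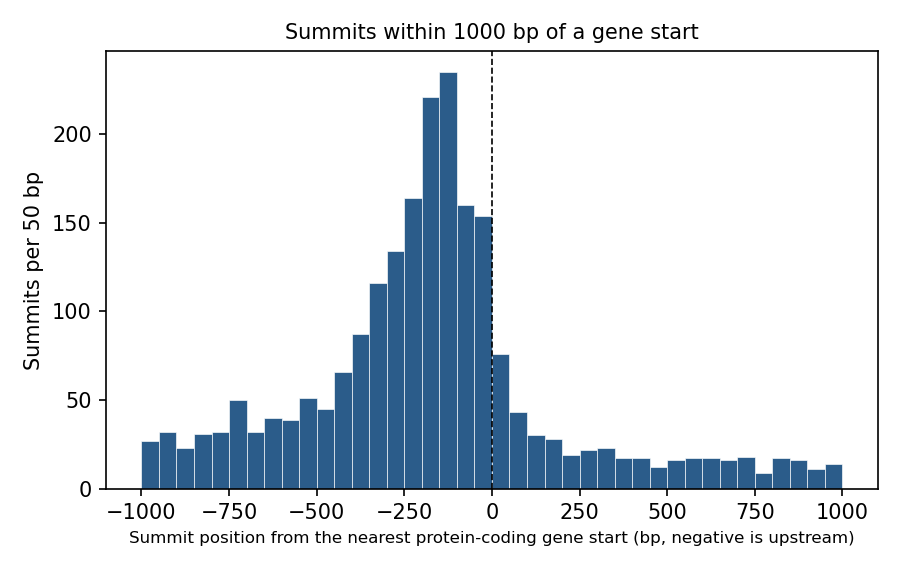
Number of conservative-list summits per 50 bp (y axis) by position from the nearest protein-coding gene start within 1000 bp (x axis, bp, negative is upstream; dashed line, the start). Of the 2177 summits, 1739 lie upstream, with the median at -174 bp.

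Coding sequence was avoided and non-coding RNA genes were overrepresented. The 500 bp upstream of protein-coding genes held 33.3% of summits against 9.18% of shifted ones (3.63-fold), 5' UTRs 3.44% against 1.65% (2.08-fold), and non-coding RNA genes 5.89% against 0.901% (6.54-fold). Coding exons held 3.53% against 23.4% (0.151-fold; 0.608% among the stronger 2138 peaks), 3' UTRs 1.03% against 2.84% (0.363-fold) and introns 24.2% against 33.3% (0.728-fold). Each of these classes had an adjusted permutation p of 0.000233 over the 7 classes, the smallest possible here. The rest of the genome held 28.6% against 28.8% (adjusted permutation p = 0.812). The signal at gene starts was higher, with a median of 121 against 105 elsewhere (difference 15.5; two-sided permutation p = 2e-05, the smallest the resamples can give). Among the stronger 2138 peaks this difference was -3.32 (permutation p = 0.456), and at a global IDR of at most 0.001 it was 3.13 (permutation p = 0.474). The stronger peaks were chosen by the signal itself, so they are no independent check of it. In the replicates' own lists the difference was 5.05 and 4.19 (two-sided permutation p = 0.00396 and 0.022).

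Transfer RNA genes stood out among the non-coding genes. Of 612 tRNA genes, 371 (60.6%, 95% Wilson interval 56.7 to 64.4) had a summit within 500 bp of their start, 13.9 times the 4.37% of shifted summits. In the replicates' own lists the share was 48.4% and 52.1% (mean 50.2% ± 2.66, SD, n = 2). The nearest summit lay at a median of 16 bp into the tRNA gene (quartiles -13 and 40 bp), and the 329 summits near tRNA genes had a median signal of 157 against 108 for the rest. By chromosome the share ran from 39.7% of 78 tRNA genes on V to 75.4% of 57 on II, with 179 of 276 (64.9%) on X. tRNA genes whose sequence occurs more than once in the genome had a summit more often (65.3% of 472) than those whose sequence occurs once (45% of 140; Fisher's exact p = 2.15e-05).

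Several other types of non-coding RNA genes followed at a lower level. Any summit within 500 bp of their start counted, and summits that also lay at a protein-coding gene start were not set apart. snoRNA genes, whose products guide the modification of ribosomal RNA, had a summit in 108 of 346 cases (31.2%, 7.69-fold over shifts), snRNA genes in 23 of 129 (17.8%, 5.06-fold), microRNA genes in 43 of 261 (16.5%, 3.95-fold), genes annotated as ncRNA in 1117 of 7764 (14.4%, 3.50-fold) and lincRNA genes in 22 of 194 (11.3%, 2.77-fold). piRNA genes, which lie mostly in clusters on chromosome IV, were below the shifted level, with 162 of 15363 (1.05% against 3.25%). In the replicates' own lists the shares were 9.45% and 10.7% for ncRNA genes, 5.67% and 7.73% for lincRNA genes, and 0.540% and 0.846% for piRNA genes. The adjusted permutation p was 0.000257 for tRNA genes and for each of these 6 types, the smallest possible over 9 types. Antisense RNA genes (3 of 100; 3.00% against 3.66%) did not pass the test (adjusted permutation p = 1), nor did ribosomal RNA genes (0 of 20, with an upper Wilson limit of 16.1%; adjusted permutation p = 1). The count of 0 holds for the conservative list: 3 ranked peaks that reach its lowest score but are absent from it have summits 228, 137 and 114 bp from the starts of rrn-4.2 genes on V (WBGene00077469, WBGene00077470 and WBGene00077475), which encode 5S ribosomal RNA.

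**Figure D3:**
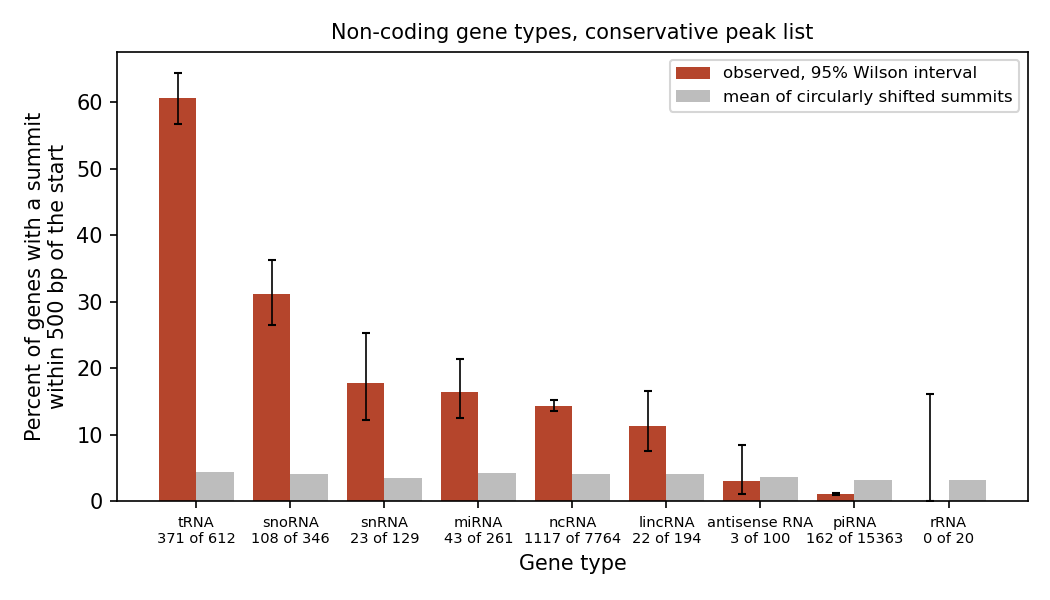
Percent of genes of each non-coding type with a conservative-list summit within 500 bp of their start (red bars, with 95% Wilson intervals) beside the mean over circularly shifted summits (grey bars); the x axis gives the types with their counts. tRNA genes stand at 60.6% and snoRNA genes at 31.2%, while piRNA genes stand at 1.05%, below their shifted level of 3.25%.

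Cytosolic ribosomal protein and translation factor genes were marked far more often than other genes. Of 28 gene lists, 13 had a higher share of members with a summit within 500 bp of the start than all other protein-coding genes, 7 a lower share, and 8 did not pass the test (Fisher's exact tests, two-sided, adjusted over the 28 lists). Cytosolic ribosomal protein genes led with 58 of 81 (71.6% against 9.53% of other genes, odds ratio 23.9, Fisher's exact adjusted p = 1.81e-39), among them rpl-3, rpl-20, rpl-35 (signal 734) and rpl-15 (728). The replicates gave 59.3% and 69.1% (mean 64.2% ± 6.98, SD, n = 2). With a 250 bp distance the odds ratio was 3.15 (Fisher's exact adjusted p = 0.00163); where each summit counted for the nearest start alone it was 9.41 (Fisher's exact adjusted p = 1.07e-17). Translation factor genes followed with 17 of 40 (42.5%, odds ratio 6.87, Fisher's exact adjusted p = 2.53e-07), including iff-2 (647), the homolog of eIF5A, eef-1A.2 (371) and eef-1G (339); eif-1 and eef-1B.2 had none. Mitochondrial ribosomal protein genes had 13 of 70 (18.6%, odds ratio 2.11, Fisher's exact adjusted p = 0.0339), led by mrps-7 (348). That call ended in the other thresholded series list (odds ratio 1.70, Fisher's exact adjusted p = 0.144) and where each summit counted for the nearest start alone (1.28, Fisher's exact adjusted p = 0.597). Aminoacyl-tRNA synthetase genes had 8 of 31 (25.8%, odds ratio 3.22, Fisher's exact adjusted p = 0.0147), led by ears-2 (344). In each replicate's own list the share was 9.68% (odds ratios 1.66 and 1.36).

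Genes of energy supply, protein folding and splicing were also marked more often. The respiratory chain and ATP synthase list had 21 of 40 (52.5%, odds ratio 10.3, Fisher's exact adjusted p = 8.35e-11), with cox-5A, cox-5B (526) and atp-1 (365). Chaperone genes had 28 of 65 (43.1%, odds ratio 7.07, Fisher's exact adjusted p = 2.24e-11), with cct-8 (669) and cct-1 (443) of the cytosolic chaperonin and the Hsp70 genes hsp-1 (519.6) and hsp-3 (498); cct-3 and cct-4 had none. Splicing factor genes had 17 of 38 (44.7%, odds ratio 7.52, Fisher's exact adjusted p = 1.16e-07), with snr-4 (348), and rsp-1 and rsp-2, which share a summit (284). Proteasome subunit genes had 9 of 33 (27.3%, odds ratio 3.47, Fisher's exact adjusted p = 0.00708), with rpn-3 (224), and vacuolar ATPase genes 6 of 20 (30%, odds ratio 3.96, Fisher's exact adjusted p = 0.0157), with vha-12 (347).

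Several lists of chromatin and cell division genes were higher as well. DREAM complex and synMuv B genes, which repress germline and cell cycle genes in the soma, had 8 of 14 (57.1%, odds ratio 12.3, Fisher's exact adjusted p = 3.68e-05), with lin-9 (481), lin-54 (462), lin-53 (351) and lin-35 (229), the retinoblastoma homolog. DNA replication and cell cycle genes had 15 of 44 (34.1%, odds ratio 4.80, Fisher's exact adjusted p = 3.12e-05), with rfc-4 (313) and pcn-1 (304), which encodes PCNA. The hmg genes had 4 of 9 (44.4%, odds ratio 7.39, Fisher's exact adjusted p = 0.0143) and SWI/SNF complex genes 3 of 7 (42.9%, odds ratio 6.93, Fisher's exact adjusted p = 0.0339), namely swsn-1 (185), swsn-3 (182) and swsn-6 (150.1). The 4 hmg genes include the tagged gene hmg-1.1 itself, and the list was not tested without it.

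Large families of environmental and sensory genes were nearly empty. Chemoreceptor genes had 5 of 1308 (0.382% against 10.4%, odds ratio 0.0329, Fisher's exact adjusted p = 8.62e-51), among them sri-5 (257) and srh-16 (242). Peaks of any rank also lay near fewer of them, at 19.3% of chemoreceptor genes against 57.5% of the others. Where at least 95% of the 32-mers around the start are unique in the genome, the count was 4 of 1069 chemoreceptor genes against 1753 of 15598 others. Genes of F-box and MATH domain proteins had 8 of 395 (2.03%, Fisher's exact adjusted p = 5.77e-09), C-type lectin genes 4 of 240 (1.67%, Fisher's exact adjusted p = 3.03e-06), and cytochrome P450 and UDP-glucuronosyltransferase genes 1 of 141 (0.709%, Fisher's exact adjusted p = 3.46e-05), the exception being ugt-46.

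Of the remaining lists, 3 were marked less often and 8 did not pass the test. Cuticle collagen genes, which epidermal cells transcribe in each larval stage, had 6 of 176 (3.41%, Fisher's exact adjusted p = 0.00478), with col-85 (472) and col-72 (247) the strongest. Neuropeptide and insulin genes had 4 of 140 (2.86%, Fisher's exact adjusted p = 0.00545), with flp-23 (168), and sperm protein genes 1 of 72 (1.39%, Fisher's exact adjusted p = 0.0147), namely spe-39. In each replicate's own list 0.714% of neuropeptide and insulin genes had a summit, against 6.06% and 7.30% of all protein-coding genes. The neuron list had 9 of 45 (20%, odds ratio 2.31, Fisher's exact adjusted p = 0.0504), with syd-2 (183), and passed as higher in 4 of 14 alternatives, with an odds ratio of 2.89 where each summit counted for the nearest start alone (Fisher's exact adjusted p = 0.0154). Body wall muscle had 7 of 37 (18.9%, odds ratio 2.16, Fisher's exact adjusted p = 0.110), with pat-4 (292). Histones had 11 of 81 (13.6%, odds ratio 1.45, Fisher's exact adjusted p = 0.300), with his-37 (435), and passed as higher in the other thresholded series list (odds ratio 2.07, Fisher's exact adjusted p = 0.0243). In the replicates' own lists the shares were 4.94% and 13.6% for histones, and 2.27% and 4.55% for germline and meiosis genes. Germline and meiosis genes had 4 of 44 (9.09%, Fisher's exact adjusted p = 1), homeobox genes 6 of 79 (7.59%, Fisher's exact adjusted p = 0.757), nuclear hormone receptor genes 18 of 269 (6.69%, Fisher's exact adjusted p = 0.119; 0.0242, as lower, with a 1000 bp distance), epidermal and heterochronic regulators 1 of 15 (6.67%, Fisher's exact adjusted p = 1), namely lin-14, and intestine genes 1 of 30 (3.33%, Fisher's exact adjusted p = 0.401), namely erm-1.

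Several list calls depended on the setting. Of 14 alternatives for each list, the call ended or turned in 9 for mitochondrial ribosomal proteins, 7 for aminoacyl-tRNA synthetases, 6 for sperm proteins, 3 each for proteasome subunits and SWI/SNF genes, 2 for vacuolar ATPase, and 1 each for hmg genes, cuticle collagens and neuropeptides. The other 11 called lists kept their call in all 14. Where members of a list within 10 kb of each other counted once and the other genes were grouped into 10 kb bins, 7 lists were higher in place of 13, and the calls ended for mitochondrial ribosomal proteins, aminoacyl-tRNA synthetases, proteasome subunits, vacuolar ATPase, hmg genes and SWI/SNF genes (adjusted Fisher's exact p from 0.0864 for hmg genes to 0.514 for mitochondrial ribosomal proteins). These losses came with the background: the share of other groups with a summit was 16.4% to 16.5% beside these 6 lists, while the aminoacyl-tRNA synthetase, proteasome, hmg and SWI/SNF lists had no members to merge and kept 8 of 31, 9 of 33, 4 of 9 and 3 of 7. The same rise in the background works towards calls of a lower share. Within single replicates the call ended for aminoacyl-tRNA synthetases in both lists (adjusted Fisher's exact p = 0.505 and 0.551), for mitochondrial ribosomal proteins, proteasome subunits and cuticle collagens in replicate 1 (0.102, 0.0728 and 0.0606), and for sperm proteins in replicate 2 (0.202). With a 250 bp distance the vacuolar ATPase odds ratio turned to 0.787 and the calls ended for aminoacyl-tRNA synthetases, SWI/SNF genes, sperm proteins and neuropeptides (adjusted Fisher's exact p = 0.0731, 0.104, 0.189 and 0.0838); among the stronger 2138 peaks the aminoacyl-tRNA synthetase odds ratio turned to 0.541.

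**Figure D4:**
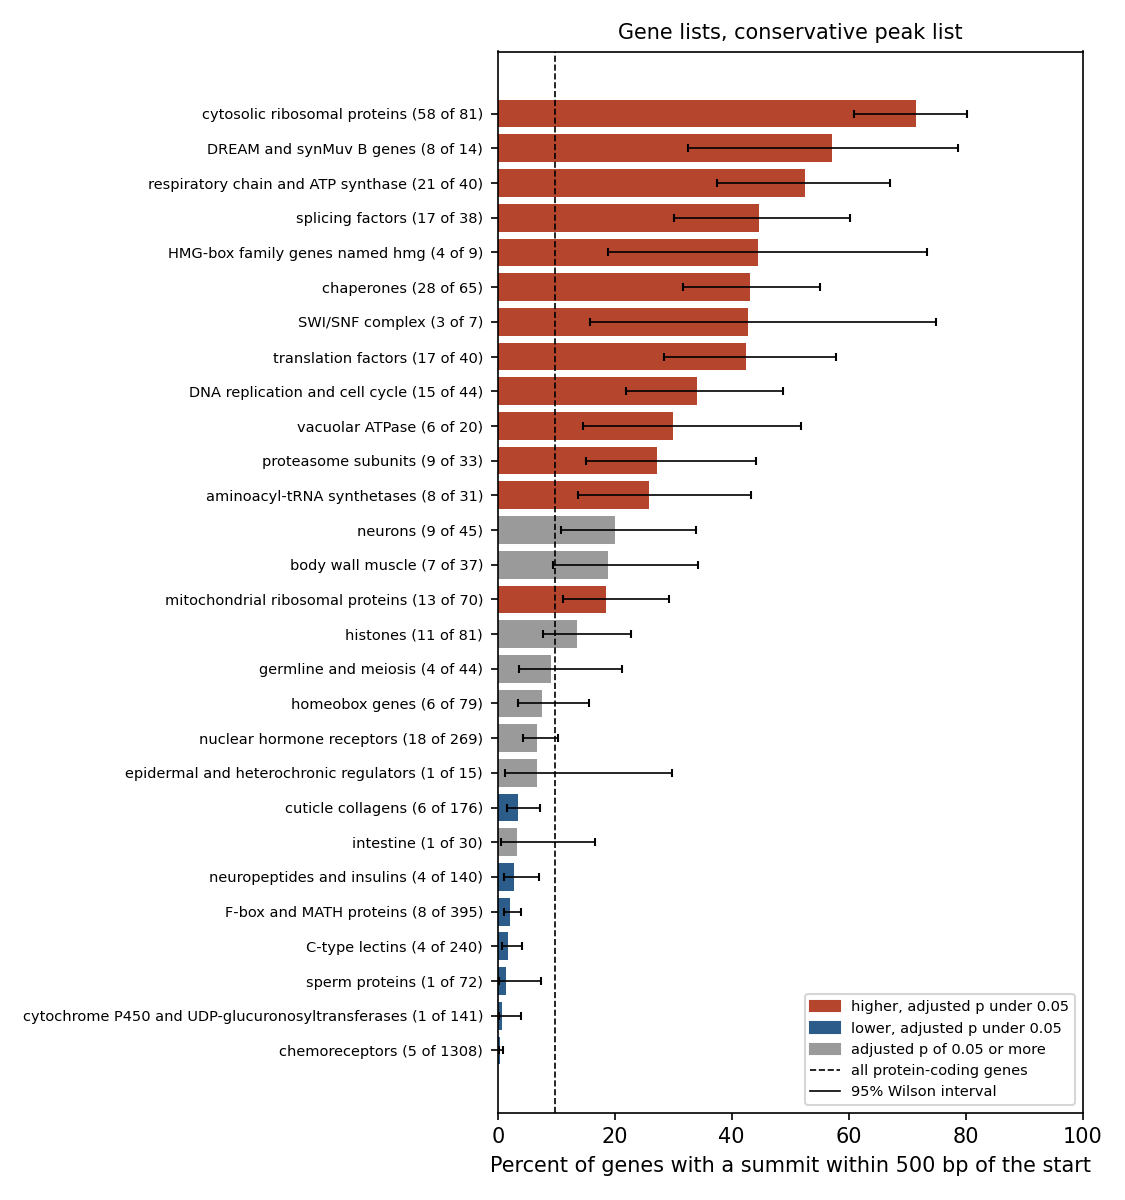
Percent of the protein-coding genes of each of the 28 lists with a conservative-list summit within 500 bp of their start (x axis), with 95% Wilson intervals; red and blue bars are lists higher or lower than all other genes at an adjusted p under 0.05, grey bars the rest, and the dashed line all protein-coding genes (9.78%). Cytosolic ribosomal proteins lie at 71.6% and chemoreceptors at 0.382%.

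Chromosomes differed in peak density. Chromosomes III, X and I held 53.0, 52.8 and 51.5 peaks per Mb, against 43.0 on II, 34.2 on IV and 27.6 on V. On X, 308 of 2731 protein-coding genes (11.3%) had a summit within 500 bp of their start, against 9.55% of 17242 autosomal genes (odds ratio 1.204, Fisher's exact p = 0.00553). This call ended without the chemoreceptor, F-box and lectin lists (odds ratio 1.09, Fisher's exact p = 0.176) and with a 250 bp distance (odds ratio 1.09, Fisher's exact p = 0.308). In the central segment of the autosomes, each divided into equal left, central and right segments, 10.4% of genes had a summit against 9.05% in the outer segments (odds ratio 1.16, Fisher's exact p = 0.00508). That call ended in both single replicates (odds ratios 1.11 and 1.064, Fisher's exact p = 0.116 and 0.311) and without the same 3 families (1.059, Fisher's exact p = 0.286).

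Genes with a divergent neighbour were marked more often than others. A gene whose start faces another start on the opposite strand within 1000 bp had a summit within 500 bp in 784 of 3539 cases (22.2%), against 935 of 12860 other genes (7.27%; odds ratio 3.63, Fisher's exact p = 1.15e-123, two-sided). Replicate odds ratios were 3.79 and 3.52. A single summit can count for both partners, and where each summit counted for the nearest start alone the odds ratio was 1.90. Genes whose start follows the end of a same-strand gene within 500 bp, the arrangement of downstream operon genes, had a summit in 235 of 3574 cases (6.58%; odds ratio 0.898, Fisher's exact p = 0.162). At a 250 bp distance the odds ratio turned to 1.25 (Fisher's exact p = 0.0128). It passed as lower in 4 of 11 alternatives, with 0.788 at a 1000 bp distance (Fisher's exact p = 0.000261).

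Summits were rich in G+C and in GA repeats. The windows centred on summits had a median G+C content of 48.5%, against 35.1% in windows of the same size 500 bp to either side, a median difference of 12.9 points, with 3761 summits higher than their flanks and 461 lower. The exact binomial p lay at 1e-300, the floor set in the code. Of all 6-mers, 869 were more frequent at summits and 614 less frequent (exact binomial sign tests, adjusted over all 6-mers). GAGAGA occurred in 28.2% of summit windows and 5.68% of flank windows, AGAGAG in 24.1% and 4.40%, and ACGCAG in 17.3% and 2.29%. CGTCTC, AGAGAC, GACGCA, AGACGC, CGCAGA, AAGAGA and CGAGAG completed the 10 with the smallest p, with 13.5% to 21.7% of summit windows. In the replicates GAGAGA was in 31.0% and 29.6% of summit windows, and ACGCAG in 18.9% of both.

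The 10 depleted 6-mers with the smallest p were all made of A and T except for TCAAAA (10.7% of summit windows against 29.3% of flanks). AAAATT fell from 42.8% of flanks to 14.7% of summits, AAAAAT from 48.9% to 20.8%, TTAAAA from 27.8% to 7.29%, and AAAAAA from 42.9% to 22.4%. The others were TAAAAA, AAATTT, AAATTA, ATTTTA and TTTAAA, the last at 4.58% of summits and 18.3% of flanks. Summit windows are richer in G+C than their flanks. Neither the depleted 6-mers nor the counts of higher and lower 6-mers were compared with windows of equal G+C content. Summit windows with GAGAGA also held ACGCAG more often than those without (27.4% against 13.3%, odds ratio 2.46, adjusted Fisher's exact p = 1.23e-25), and were less often near a tRNA gene start (3.23% against 9.44%, adjusted Fisher's exact p = 4.76e-13). They were also less often near a protein-coding gene start (33.6% against 41.2%, adjusted Fisher's exact p = 8.44e-06) and on X (18.5% against 23.2%, adjusted Fisher's exact p = 0.000853).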

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

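The test of strongly transcribed loci was chosen only after its result was seen, and the test of unique start windows was added after the test of ranked peaks at chemoreceptor genes had come out as a loss of reads predicts, though before its own result. The design has 1 group, and no biological explanation was tested for the patterns weighed in this part.

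The ranked list of both replicates holds 4324 peaks at or above the lowest score of the conservative list, and 47 of them (1.09%, 95% Wilson interval 0.818 to 1.44) are absent from that list. They stood out because a signal appears in data that the comparisons do not use. Their median signal is 121, against 110.5 for the conservative list, and they include the strongest ranked peak of all (X, 15810956 to 15811164, signal 1376). Another 3 lie near rrn-4.2 genes on V, where the conservative list has no summit at any of the 20 ribosomal RNA genes. The thresholded lists were also derived from a further file that is not described. Whether the 47 peaks were taken out on purpose through that file is unknown, so they may not be overlooked sites.

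tRNA gene starts hold summits far more often than the starts of other gene types. Sharing of reads between identical copies predicted that tRNA genes with a unique sequence would stay within the shifts. Of these 140, 45% had a summit, above the 7.86% upper limit of shifts (permutation p = 0.0002, the smallest the shifts can give). Multicopy genes stood higher at 65.3%. These values argue against sharing between fully identical copies as the whole cause, unless the summits belong to other tRNA genes within 500 bp, which was not tested. A gene with a unique sequence can also resemble other copies over most of its length, so sharing between near-identical copies stays open and may add to the excess. G+C content is argued against as well: windows of the same G+C content more than 1000 bp from tRNA genes had a summit in 9.66% of cases, against 60.6% (Fisher's exact p = 5.23e-157). Signal at strongly transcribed loci that has nothing to do with the tagged protein stays open: body wall muscle genes had an odds ratio of 2.16 that did not pass the test (adjusted Fisher's exact p = 0.110), while cuticle collagens (0.323, adjusted Fisher's exact p = 0.00478), sperm proteins (0.129, p = 0.0147) and intestine genes (0.318, p = 0.401, not past the threshold) lay on the other side. Cytosolic ribosomal proteins (23.9), the respiratory chain (10.3) and translation factors (6.87) had high odds ratios, which goes with it, but how strongly each list was transcribed in these larvae was not measured. The sperm protein call ended in 6 of 14 alternatives, and repeated sequence was not tested for the sperm, collagen or intestine genes.

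GA-rich and ACGCAG-like 6-mers were more common at summits than in their flanks. G+C content is argued against as the whole cause, since the 10 leading 6-mers were still a median of 2.81 times as frequent at summits as in nearby windows of equal G+C content. Summits at tRNA genes are argued against, since 10 of the 10 were called higher without them. Many of these 6-mers overlap in sequence, so they are not 10 separate checks. Long GA repeats are argued against for GAGAGA, since without windows holding 6 or more GA units the 6-mer was in the summit alone 5.82 times as often as in the flank alone (adjusted exact binomial p = 3.90e-148). Whether the tagged protein or another factor at these sites prefers such sequence stays open.

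Cytosolic ribosomal protein genes often hold summits and chemoreceptor genes rarely do. For the first, summits of divergent neighbours are argued against as the whole cause. Among genes without a divergent partner, 21 of 33 ribosomal protein genes had a summit (odds ratio 23.2, Fisher's exact p = 1.04e-16). Members with a divergent partner were not covered by this test. Where each summit counted for the nearest start alone, the odds ratio of the full list was 9.41 in place of 23.9. Summits nearer to the starts of other genes may therefore add to the excess. For the second, chemoreceptor genes had any ranked peak 0.336 times as often as other genes, which is what a loss of reads between paralogs predicts. Repeated sequence, which such a loss needs, is nevertheless argued against as the whole cause, because among genes whose start windows are at least 95% unique 32-mers the odds ratio of chemoreceptor genes was 0.0297 (Fisher's exact p = 5.82e-47), and this later test is what that reading rests on. Signal that follows transcription or open chromatin in general stays open and was not tested for these lists.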

How the results depend on the processing

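In this part the alternatives of 1 summit per merged region, a q-value of at most 0.05, a global IDR of at most 0.001, leaving out summits near tRNA genes and counting the nearest start alone were chosen after seeing the data. Of the values that answer a comparison, 95 were kept under the settings fixed beforehand and 58 under the added ones. A tested value was kept if its direction and side of the threshold stayed, or if it passed the threshold in neither setting. A count was kept if it changed by at most 1.5-fold. The number of lists called lower, which ran from 5 to 7, was therefore kept throughout. Values not kept are given here, and the cause was not tested except where stated. A global IDR of at most 0.01, also fixed beforehand, left all 4277 peaks in place and so tested nothing. Leaving out summits near tRNA genes was first run for the non-coding types too, where it sets the tRNA share to 0 by construction, and is not counted there. The depth of the samples is unknown, so its effect on the length of the lists could not be measured.

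With the stronger 2138 peaks the odds ratio of central against outer genes fell below the threshold (1.069), that of genes after a same-strand gene end passed it (0.749), and the signal difference at gene starts turned to -3.32, not past the threshold. These peaks were chosen by signal, so they are no independent check of the signal difference. At a global IDR of at most 0.001 the central odds ratio, the same-strand odds ratio and the signal difference were 1.088, 0.818 and 3.13. At a distance of 250 bp the X odds ratio was 1.088 and the central one 1.034, both no longer past the threshold, and genes after a same-strand gene end turned to 1.25; at 1000 bp they passed at 0.788. Without the 3 gene families the X odds ratio was 1.095 and the central one 1.059. In the single replicates the central odds ratio ran from 1.064 to 1.11, not past the threshold, and that of genes after a same-strand gene end from 0.758 to 0.852, past it in replicate 2 alone. With clustered members counted once and other genes in 10 kb bins, 7 lists were higher in place of 13; the binning raised the background share, to 16.5% for the SWI/SNF list, whose own 3 of 7 stayed in place. With summits near gene starts only, 578 6-mers were higher in place of 869. Across the regions of the conservative list rho was 0.822.

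Of gene lists, named 6-mers, annotation classes and non-coding types, 466 values kept their call under the settings fixed beforehand, 23 became weaker and 3 stronger, and 263, 8 and 4 did so under the added ones. Reversed, with a call before or after, were the odds ratio of aminoacyl-tRNA synthetases among the stronger peaks (0.541) and of vacuolar ATPase genes at 250 bp (0.787). Odds ratios that changed direction without a call on either side are among the values kept. That of histones, 1.45 in the main result, fell as low as 0.577. That of germline and meiosis genes, 0.922 in the main result, rose as high as 1.27.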

Other observations

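In this part all tests and counts on the X chromosome were chosen after the strongest peaks had been seen, while the sequence searched for and its prediction were fixed before that search was run. The test of ranked peaks outside the conservative list was also chosen after the data had been seen.

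Strong regions were concentrated on X, and most of those on X lay away from gene starts. Of the 100 strongest regions of the conservative list, 40 lay on X, against 838 of the other 3908 (40.0% against 21.4%, odds ratio 2.44, Fisher's exact p = 3.84e-05), and 34 of these 40 were more than 500 bp from any protein-coding gene start. In each replicate's own list 40 of the 100 strongest regions were on X, 33 of them away from starts. Of the 25 strongest, 15 were on X, a larger share than among the other regions (Fisher's exact p = 4.01e-05). All 15 were away from starts. Whether strong X regions lay away from starts more often than other X regions was not tested. Of all X regions, 597 lay away from starts and 281 at starts. The 597 X regions away from starts had a median signal of 111 (quartiles 83.6 and 198), close to the median of 109.5 (80.8 and 171) for the 1819 autosomal ones. At gene starts the medians were 139.8 for 281 X regions and 122.2 for 1311 autosomal ones; neither difference was tested.

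A hypothesis is that some of these sites are those where the dosage compensation complex is recruited to X in hermaphrodites. The core of its recruitment motif, GCGCAGGG, was searched for within 100 bp of the summits. It was found in 11 of the 34 strong X regions away from starts (32.4%, 95% Wilson interval 19.1 to 49.2), in 14 of 844 other X regions (1.66%), in 1 of 60 strong autosomal regions (1.67%) and in 7 of 3070 other autosomal regions (0.228%). The odds ratio between strong and other X regions was 28.4 (Fisher's exact p = 1.60e-10). The share falls between what was predicted if the motif accounts for the pattern and what was predicted if it does not, so the motif may mark part of these sites and the rest stay open. Such sites can also be strong in immunoprecipitations of unrelated proteins, which these data cannot tell apart from binding of the tagged protein, since no sample with another tag or antibody was analysed here.

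Weaker peaks of the ranked list showed less of the features described above. Among its strongest 8406 peaks, 32.04% of summits lay within 500 bp of a gene start and 4.44% near a tRNA gene, with a median G+C difference of 10.4 points. Among its next 8406 peaks these values were 19.3%, 0.547% and 5.94 points, and among its weakest 8405 peaks they were 16.9%, 0.345% and 0.495 points. In the replicates' own ranked lists, 92.4% and 90.9% of peaks had a q-value above 0.05, so a weak ranked peak need not be a site. The 79775 ranked peaks outside the conservative list had 17.95% at gene starts, under the 18.6% of shifted summits (two-sided permutation p = 0.001).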
